A study of Mus musculus with 8 samples.

How the data were processed

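The series compared gene expression in the hearts of female and male C57BL/6 mice, a widely used inbred strain, at 2 and 8 months of age. Per the labels, total RNA from 6 whole hearts was pooled for each sex and age, which gave 4 pools. Each array compared the female pool with the male pool of the same age in 2 dyes (Cy3 and Cy5). There were 4 arrays per age, and the female pool carried Cy3 on replicates 1 and 3 and Cy5 on replicates 2 and 4.

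The deposited table holds log10 ratios, 1 value per array and probe, which the authors made with Agilent Feature Extraction version 7.1.1, per the labels; any further normalization is not given in the sources used here. The values had the form of that program's log10 ratio of Cy5 over Cy3: they were limited at 2 and -2, that is 100-fold, and every column had a deposited median of 0. The sign was checked with the sex-linked probes: Xist, Eif2s3y and Kdm5d changed sign with the dye of the female pool on all 8 arrays, so the authors had not turned the ratios. The table had 9607 rows, and 6.38 to 13.9% of the values per array were exactly 0, with 590 rows at 0 on all 8 arrays. Since no other value recurred more than 2 times in a column, an exact 0 was treated as no measurement. The table holds no intensities, so signal over background is unknown, and the number of arrays limits the precision.

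Ratios were converted from log10 to log2 and turned to female over male by changing the sign where the female pool carried Cy3. Probes were named from the platform annotation, updated by gene ID through the RefSeq table of the mouse assembly GRCm38.p6, which was used for names alone. Of the rows, 6671 had 1 gene symbol (6600 matched the RefSeq table and 71 kept the platform symbol), 400 had several and 2536 had none; the last 2 kinds were kept under their probe number. Rows with the same symbol were averaged on each array. A row was tested when each age had values on at least 3 of the 4 arrays, with both dye orientations, which left 7812 rows, 5851 of them with a symbol. The value of an age is the mean of its 2 dye orientations, in which a dye effect cancels. Of the 135 named genes, 7 had more than 1 probe, and the probes disagreed in sign for Per3 at 2 months and for Clock at 8 months.

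The 4 arrays of an age measured the same 2 RNA pools and were counted as 1 replicate. The SD given beside a value at 1 age is the spread of these technical arrays, not of animals. The comparison of the sexes over both ages used limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, two-sided) on the 2 age means, with n = 2 pairs of pools and Benjamini-Hochberg adjustment; an adjusted p below 0.05 was called. The 7 called rows also had 1 sign on all arrays, which was not asked of genes adjusted over a list alone. No test across animals exists at 1 age, or for the difference of the ages. There, rows were listed by size: at least 1.5-fold with 1 sign on all arrays of the age, and for the difference at least 1.5-fold with no overlap of the arrays of the 2 ages. With no difference and independent arrays, 12.5% of rows would have 1 sign on 4 arrays and 2.86% would have no overlap. The arrays were not independent, so these shares are no expectation for these data: at 2 months, arrays of the same dye orientation correlated at 0.783 and 0.836 and arrays of opposite orientation at -0.026 to 0.219. Some p-values in the closing section come from fits over single arrays and measure technical spread only.

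28 gene lists covering sex-linked genes, heart functions, signalling and other cell types were fixed before the data were examined, as were the groups, the tests, the rule for named genes and the alternative settings described below, unless stated otherwise. Lists of at least 3 measured genes were tested over both ages with camera in limma, at a preset correlation of 0.01, with adjustment over the 27 tested lists. Adjusted p-values with a correlation estimated from the data are given beside the calls. They rest on 1 residual degree of freedom, and no list was called with them, the X escape list included. They cannot tell whether a call depends on the preset correlation. At 1 age a list's median is given with its percentile among 10000 random lists of the same size, drawn from all genes without matching on level. Genes were named by this rule: over both ages up to 12 per direction among those called, topped up to 5 by the next p; at each age up to 10 per direction by size; for the age difference 5 per direction; every measured gene of the sex-linked lists; and from each other list up to 4 with the largest value over both ages. Genes named outside the rule are marked as chosen after their values were seen.

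The fit was tested on simulated data with 7812 rows, 200 of them changed. It recovered 95 of 100 rows changed 2-fold and 100 of 100 changed 4-fold, with 9 calls among unchanged rows. The size rule recovered 99% of 2-fold changes at 2 months and 91% at 8 months. The simulated rows had no trend along the feature number, and their spread was drawn from the prior that limma fitted. In the data Ogdh, at -0.998 over both ages (log2), was not called (limma adjusted p = 0.127). The simulated shares therefore do not give the power of the fit in these data. Alternatives covered centring, scaling, filters, probe averaging, thresholds, fits over single arrays and leaving out each array. Added after the data were seen were keeping values of 0, removing the trend along the feature number from each array with lowess, and taking the 8-month value from arrays 3 and 4 only.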

Results

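Sex differences in heart gene expression were measured in 1 pool of 6 hearts per sex at each of 2 ages, with 4 technical two-colour cDNA arrays per age. On 6 of the 8 arrays the ratios were even along the feature number, the order of the probes on the array, with a running median that varied by 0.049 to 0.083 (SD, log2). On replicates 1 and 2 at 8 months it varied by 0.51 and 0.82, and the interquartile range of the ratios was 1.18 and 1.56 against 0.30 to 0.46 on the other arrays. These 2 arrays had opposite dye orientations, so the trend partly cancelled in the 8-month mean but widened its spread. Values at 8 months are therefore also given from replicates 3 and 4 where they matter.

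**Figure D1:**
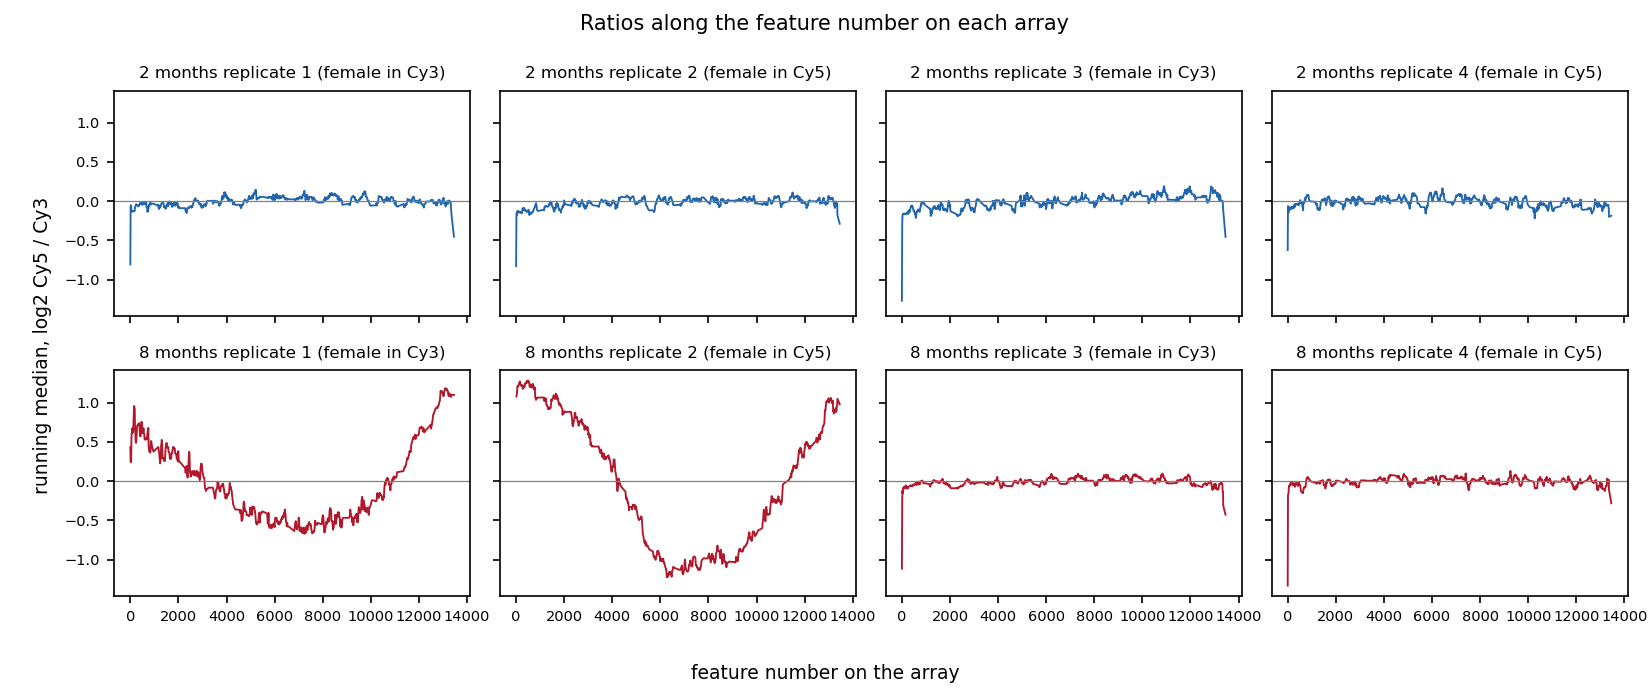
Running median of the log2 ratio of Cy5 over Cy3 against the feature number, with 1 panel per array, 2 months in the upper and 8 months in the lower row. Replicates 1 and 2 at 8 months show a trend with an SD of 0.51 and 0.82, against at most 0.083 on the other 6 arrays.

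Sex-linked transcripts separated the pools at both ages. Xist, the RNA that silences 1 X chromosome in females, was higher in the female pool by 2.44 ± 0.89 at 2 months and 3.45 ± 0.85 at 8 months (log2, SD, n = 4 arrays). The Y-linked genes Kdm5d, a histone demethylase, and Eif2s3y, a translation initiation factor subunit, were lower in the female pool, Kdm5d by -2.43 ± 0.78 and -2.88 ± 1.04 and Eif2s3y by -3.18 ± 0.81 and -1.87 ± 0.55. Of the 7 measured X-linked genes on the list of those that escape inactivation, 1 rose and 6 did not pass the test over all genes; adjusted over the list alone, 5 rose, of which Xist and Car5b had 1 sign on all 8 arrays and Ddx3x, Kdm6a and Pbdc1 did not at 8 months. The list shifted upward with a median of 0.51 (camera adjusted p = 5.93e-11; adjusted p = 0.94 with an estimated correlation). Beside Xist, Car5b was at 0.93 over both ages, Pbdc1 at 0.53, Ddx3x at 0.51, Kdm6a at 0.43, Jpx at 0.23 and Usp9x at -0.04. The 2 measured Y-linked genes were too few for a list test; 1 fell over all genes and 2 fell adjusted over the list alone.

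**Figure D2:**
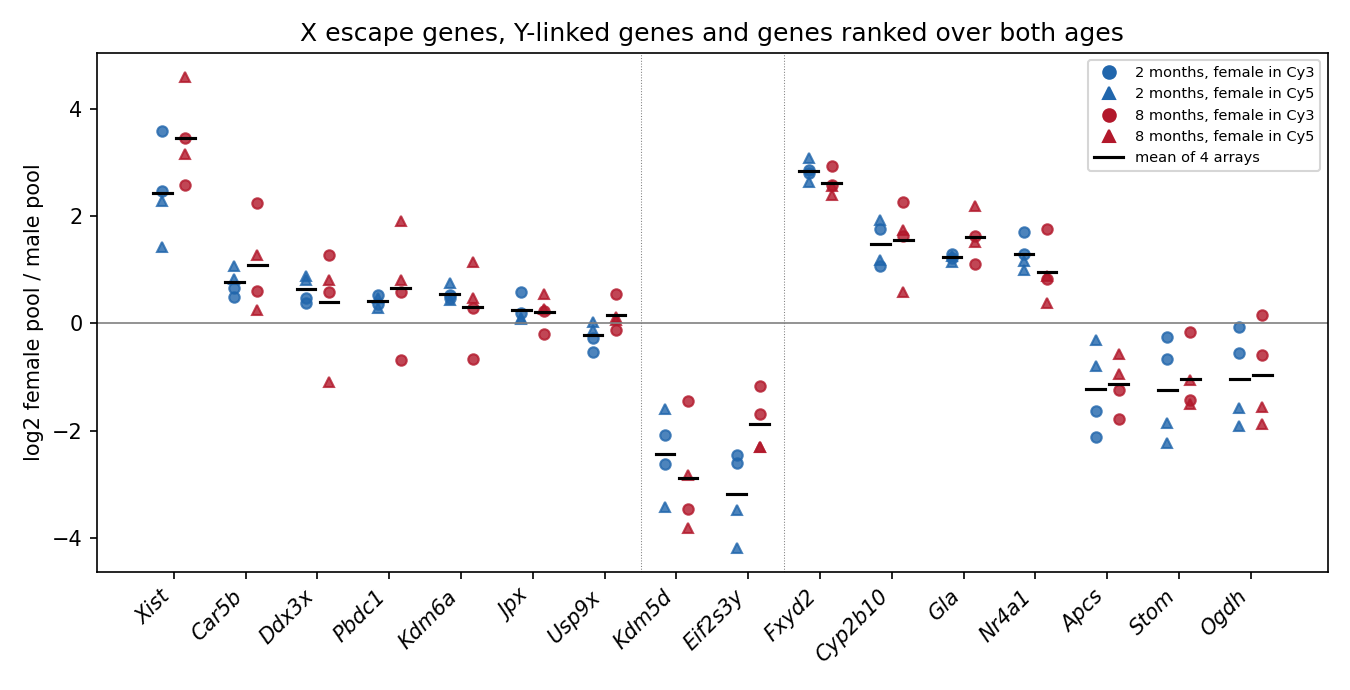
Log2 ratio of female over male on each array for the X escape genes, the Y-linked genes and the genes ranked first over both ages; colours are ages, symbols the dye of the female pool, and bars the mean of the 4 arrays. Xist is above 1.4 and Kdm5d and Eif2s3y are below -1.1 on all 8 arrays.

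Beyond sex-linked genes, the female pools over both ages had more Fxyd2, the regulatory gamma subunit of the sodium pump, and more Cyp2b10, a cytochrome P450 of drug metabolism. Fxyd2 rose by 2.73 ± 0.13 (log2, SE, n = 2 pool pairs; limma adjusted p = 0.00407) and was higher in the female pool on all 8 arrays. Cyp2b10 rose by 1.52 ± 0.12 (limma adjusted p = 0.0244), also on all 8 arrays. Xist rose by 2.94 ± 0.24 (adjusted p = 0.0244, limma) and Kdm5d fell by 2.66 on this scale (SE 0.15, adjusted p = 0.00501, limma). The other 3 called rows had no gene symbol here: probe 9946 was higher by 6.37, at the limit of the scale on some arrays, probe 11781 was higher by 2.24, and probe 12917 was lower by -4.98, at the limit on replicate 1 at 8 months. In all, 7 of 7812 rows were called, 5 higher and 2 lower in females, and 811 had an unadjusted p below 0.05.

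The next genes by p did not pass the test. On the female side they were Gla, the X-linked lysosomal alpha-galactosidase A, at 1.42 ± 0.15 (SE; limma adjusted p = 0.0757) and Nr4a1, an orphan nuclear receptor, at 1.12 ± 0.14 (limma adjusted p = 0.127). On the male side they were Apcs, serum amyloid P, at -1.17 ± 0.12 (limma adjusted p = 0.0798) and Stom, the membrane protein stomatin, at -1.14 ± 0.13 (limma adjusted p = 0.109). They were followed by Eif2s3y at -2.52 ± 0.30 (limma adjusted p = 0.115) and Ogdh, a subunit of the 2-oxoglutarate dehydrogenase complex, at -0.998 ± 0.12 (limma adjusted p = 0.127). With the 8-month value taken from arrays 3 and 4 only, 1 row was called, probe 9946, although Fxyd2 was at 2.71, Xist at 2.87, Cyp2b10 at 1.58 and Kdm5d at -3.03 and their limma adjusted p-values were then 0.172 to 0.489. Removing the trend along the feature number also left probe 9946 alone, with Fxyd2 at 2.66, Xist at 2.87, Cyp2b10 at 1.58 and Kdm5d at -2.60. Leaving out replicate 1 or 4 at 8 months gave 88 or 105 calls. Without replicate 4 the limma adjusted p of probe 9946 was 1.639e-132, from 2 values per row. With 1 residual degree of freedom such a p rests on the variance prior that limma fitted. These counts therefore do not show that more rows differ between the sexes. Without replicate 4 at 2 months Xist, Cyp2b10 and Kdm5d were not called (limma adjusted p = 0.105, 0.0981 and 0.0981). Nor was Xist without replicate 3 at 2 months (limma adjusted p = 0.0693), or Cyp2b10 without replicate 1 at 2 months or 3 at 8 months (limma adjusted p = 0.114 and 0.113). With the arrays scaled to 1 spread, 3 rows were called, and Fxyd2 and Cyp2b10 were not (limma adjusted p = 0.633 and 0.412), although they were at 3.14 and 1.77. With each array centred on its median 5 rows were called and with no filter 4, in both cases without Xist (limma adjusted p = 0.081 and 0.167) and Cyp2b10 (limma adjusted p = 0.0632 and 0.126).

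Fatty acid oxidation genes were lower in the female pools as a group. All 14 measured members had negative values at both ages, with a median of -0.32 over both ages (camera adjusted p = 0.000317; adjusted p = 0.94 with an estimated correlation). None passed the test over all genes; adjusted over the list alone, 1 fell, Pdk4, the kinase that restrains pyruvate dehydrogenase, at -1.20 ± 0.22 (SE). Hadh, Acads and Acaa2, enzymes of beta-oxidation, were at -0.37, -0.36 and -0.36. Endothelial markers also shifted downward, with a median of -0.13 over 14 genes (camera adjusted p = 0.0248, and 0.94 with an estimated correlation). Their median was -0.084 at 2 months (percentile 13.5 among random lists) and -0.22 at 8 months (percentile 0.83), or -0.13 on replicates 3 and 4. At 2 months it depended on the dye: 0.0185 and 0.0709 on replicates 1 and 3, against -0.238 and -0.333 on replicates 2 and 4. None of them passed over all genes and 3 fell adjusted over the list alone: Flt1 and Kdr, receptors for vascular endothelial growth factor, at -0.60 and -0.49, and Cdh5, the cadherin of endothelial junctions, at -0.46. Of the 3, Flt1 did not have 1 sign on all arrays at either age.

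Several groups shifted upward over both ages, and for some the shift came from 1 age. None was called with an estimated correlation, a check that could hardly call any list with 1 residual degree of freedom. Glucocorticoid response genes had a median of 0.39 over 13 genes (camera adjusted p = 0.00324; adjusted p = 0.94 with an estimated correlation); none passed over all genes, and 3 rose and 1 fell adjusted over the list alone, although none of the 3 that rose had 1 sign on all arrays at 8 months. Fkbp5, a chaperone of the glucocorticoid receptor, was at 0.65, the metallothionein Mt2 at 0.54 and the secreted lipocalin Lcn2, which did not pass, at 1.24. Pdk4 was the gene that fell. Immediate early genes had a median of 0.30 over 9 genes (camera adjusted p = 0.00258; adjusted p = 0.94 with an estimated correlation); none passed over all genes and 1 rose adjusted over the list alone, Nr4a1, with Fos at 0.65, Klf2 at 0.52 and Myc at 0.36. Xenobiotic metabolism genes shifted upward (camera adjusted p = 0.0128; adjusted p = 0.94 with an estimated correlation) with a median of 0.081 over 19 genes, of which 1 rose over all genes, Cyp2b10, and 2 rose adjusted over the list alone, with Cyp2b9 at 0.79. At 2 months 14 of the 19 were positive with a median of 0.041, but at 8 months 13 were negative with a median of -0.10 (percentile 13.6 among random lists). Lymphocyte markers had a median of 0.66 over 15 genes (camera adjusted p = 0.00324; adjusted p = 0.94 with an estimated correlation), with no gene called over all genes or adjusted over the list alone, and medians of 0.69 at 2 and 0.11 at 8 months. Erythroid markers had a median of 0.42 over 4 genes (camera adjusted p = 0.00946; adjusted p = 0.94 with an estimated correlation), with none called over all genes and 1 that rose adjusted over the list alone, the carbonic anhydrase Car2 at 0.65, without 1 sign on the arrays at 8 months. Their median was 0.077 at 2 months, with 2 of 4 negative, and 0.78 at 8 months. Lung, liver and thymus markers had a median of 0.30 over 7 genes (camera adjusted p = 0.000328; adjusted p = 0.94 with an estimated correlation), with none called over all genes and 3 that rose adjusted over the list alone, led by Sftpc, surfactant protein C, at 2.44, the 1 of them with 1 sign on all arrays, and medians of 0.66 at 2 and 0.16 at 8 months. For glucocorticoid response genes they were 0.44 and 0.26, and for immediate early genes 0.074 and 0.26.

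The other 18 tested lists were not called. Contractile and metabolic genes of the heart muscle were among them, with medians over both ages of -0.094 for sarcomere genes (12 measured, camera adjusted p = 0.561) and -0.20 for glycolysis genes (10 measured, adjusted p = 0.369 by camera). They were -0.07 for respiratory chain genes (27 measured, adjusted p = 0.576 by camera) and -0.16 for calcium handling and ion channel genes (13 measured, adjusted p = 0.576 by camera). Fetal and hypertrophy genes were at -0.11 (10 measured, camera adjusted p = 0.874), and skeletal muscle markers at -0.075 (10 measured, camera adjusted p = 0.576). Atrial markers were at 0.018 (5 measured, camera adjusted p = 0.957), and renin-angiotensin and natriuretic genes at -0.014 (6 measured, camera adjusted p = 0.957). Among stromal and immune groups, extracellular matrix genes were at -0.079 (20 measured, camera adjusted p = 0.677), and smooth muscle and pericyte markers at -0.10 (10 measured, camera adjusted p = 0.148). Antigen presentation and macrophage markers were at -0.087 (19 measured, camera adjusted p = 0.148) and interferon response genes at 0.089 (12 measured, camera adjusted p = 0.957). Adipocyte markers were at 0.24 (9 measured, camera adjusted p = 0.101), and brown fat markers at -0.11 (4 measured, camera adjusted p = 0.957). Heat shock genes were at 0.052 (10 measured, camera adjusted p = 0.59) and steroid receptor and metabolism genes at 0.028 (9 measured, camera adjusted p = 0.807). Clock genes were at -0.15 (9 measured, camera adjusted p = 0.79) and cell cycle genes at 0.021 (21 measured, camera adjusted p = 0.759). Of these genes, none was called over all genes. Adjusted over the list alone, 1 interferon response gene fell, the GTPase Iigp1 at -0.82, without 1 sign on the arrays at 8 months, and none of the others passed. The median and the direction of camera differed in sign for 4 lists: interferon response, brown fat, atrial and cell cycle.

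**Figure D3:**
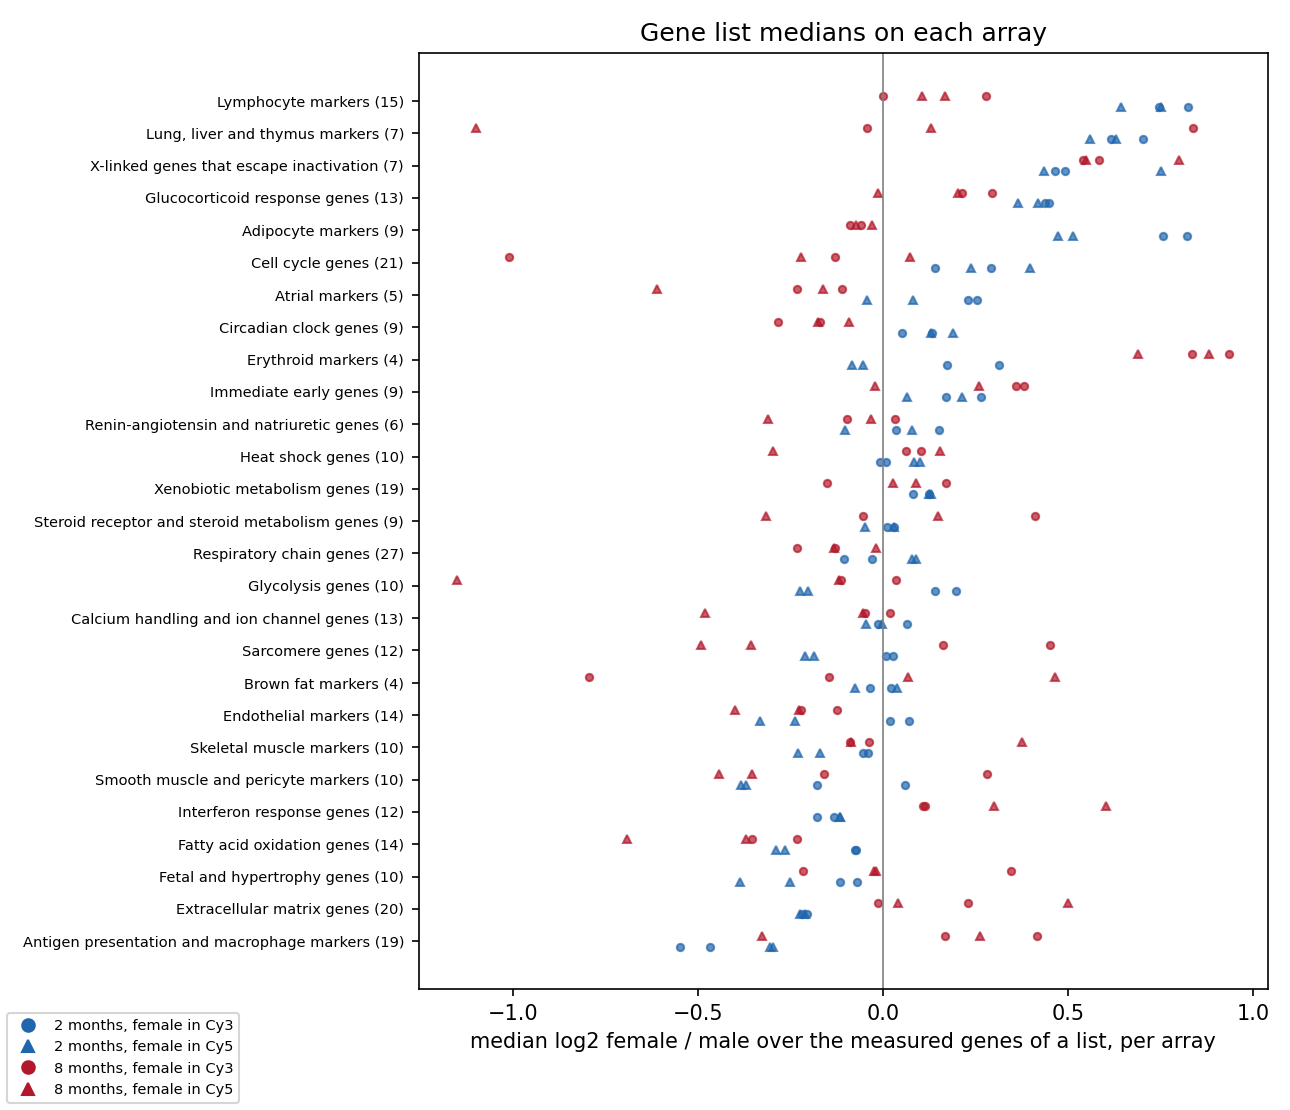
Median log2 ratio of female over male of each tested gene list on each array, with the number of measured genes in brackets; colours are ages and symbols the dye of the female pool. Antigen presentation and macrophage markers lie below 0 on all 4 arrays at 2 months, and fatty acid oxidation genes lie below 0 on all 8 arrays.

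Among rows with a gene symbol, the largest ratios at 2 months belonged to genes of developing T cells, all higher in the female pool. They were Rag1, the recombinase of antigen receptor genes, at 4.48 ± 0.60 (log2, SD, n = 4 arrays), the T cell receptor gene Tcrb-V8.2 at 4.08 ± 1.25, the co-receptor Cd8a at 3.74 ± 0.93, and Dntt, the terminal transferase, at 3.60 ± 0.61. Of the rows with no symbol, probe 9946 was at 6.345, probe 12917 at -4.338 and probe 3559 at 3.854, the last chosen after its values were seen. The adaptor Lat was at 3.22 ± 0.17 and Rasgrp1, a Ras activator of T cells, was at 2.46 ± 0.61. Tbata, a gene of the thymic stroma, was at 3.14 ± 0.41, the thymic chemokine Ccl25 at 2.91 ± 0.21, and Ucp1, the uncoupling protein of brown fat, at 2.99 ± 0.21. Fxyd2 was at 2.85 ± 0.18. Lower in the female pool, beside the 2 Y-linked genes, were Pdk4 at -1.64 ± 0.72, Stom at -1.25 ± 0.94, the transferrin receptor Tfrc at -1.24 ± 0.62 and Apcs at -1.21 ± 0.81. Also lower were the endocytic scaffold Itsn1 at -1.14 ± 0.24 (n = 3 arrays), Nsmaf at -1.07 ± 0.25, Ogdh at -1.03 ± 0.86 and Sqle, an enzyme of cholesterol synthesis, at -0.98 ± 1.43 (n = 3 arrays).

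By the size rule 326 rows differed at 2 months, 188 higher and 138 lower in the female pool, and 248 of them had a symbol. Of all rows, 35.8% had 1 sign on the 4 arrays. Lymphocyte markers had a median of 0.69 (percentile 100 among random lists), with 8 genes higher and 1 lower by the size rule. Adipocyte markers had a median of 0.44 (percentile 100), with 4 genes higher by the size rule: the lipogenic genes Fasn and Scd1 at 1.88 ± 0.23 and 1.79 ± 0.13, the lipid droplet gene Cidec at 1.71 ± 0.23 and Car3 at 1.33 ± 0.15. Of the other brown fat markers none met the size rule, with Elovl3 at -0.07, Cox7a1 at -0.08 and Ppargc1a at -0.23. Glucocorticoid response genes had a median of 0.44 (percentile 100), with 6 genes higher and 1 lower by the size rule, and cell cycle genes a median of 0.29 (percentile 100), with 3 genes higher, led by the proliferation marker Mki67 at 1.10 ± 0.28. The T cell genes and Ucp1 were higher in the same pool.

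In the same pools, most macrophage and matrix genes were lower in the female pool at 2 months, mostly by less than 1.5-fold. Of 19 antigen presentation and macrophage markers, 18 were negative, with a median of -0.44 (percentile 0), although none reached the size rule: the complement gene C1qa was at -0.80 ± 0.97, and the class II genes H2-Aa, H2-Eb1 and Cd74 were at -0.50 ± 0.17, -0.46 ± 0.18 and -0.31 ± 0.23. Of 20 extracellular matrix genes, 19 were negative, with a median of -0.22 (percentile 0.04) and 2 lower by the size rule, among them the collagen gene Col6a1 at -0.94 ± 0.52. These ratios describe 1 pool per sex and have no test across animals.

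Among rows with a gene symbol, Chil1, a chitinase-like protein, had the largest ratio at 8 months, followed by Xist. Chil1 was higher in the female pool by 4.21 ± 1.05 (log2, SD, n = 4 arrays), Jchain, the joining chain of immunoglobulins, by 2.61 ± 1.01, and Lcn2 by 2.43 ± 0.83. The chemokine Cxcl5 was higher by 1.91 ± 0.90, Timp1, an inhibitor of matrix proteases, by 1.72 ± 0.97 and the acute phase gene Saa3 by 1.69 ± 0.97. Sftpc was higher by 3.12 ± 1.65, Fxyd2 by 2.62 ± 0.23, Gla by 1.61 ± 0.45 and Nppb, the precursor of B-type natriuretic peptide, by 1.55 ± 0.60. On replicates 3 and 4 alone, Chil1 was at 3.45, Sftpc at 3.89, Jchain at 2.66, Fxyd2 at 2.56, Lcn2 at 1.99, Cxcl5 at 2.41, Timp1 at 2.13, Gla at 1.91, Saa3 at 1.14 and Nppb at 1.15. Lower in the female pool, beside the Y-linked genes, were Nefm, a neurofilament gene, at -1.58 ± 0.70 (n = 3 arrays), Zfp395 at -1.27 ± 0.85, Ctnnd2 at -1.20 ± 1.48 and Mypop at -1.19 ± 1.42 (n = 3 arrays). So were Apcs at -1.14 ± 0.51, the receptor kinase gene Kit at -1.13 ± 0.21 (n = 3 arrays), Plekhm3 at -1.11 ± 0.60 and the mitotic kinase gene Aurka at -1.07 ± 0.63. On replicates 3 and 4 alone, Zfp395 was at -0.70, Ctnnd2 at -0.42, Mypop at -0.49, Apcs at -0.91, Kit at -1.10, Plekhm3 at -1.01 and Aurka at -0.72, and Nefm had a value on replicate 4 only, at -0.99. Replicate 1, which carries the trend, had the lowest value of Ctnnd2 at -3.36 and of Mypop at -2.80, while replicate 3 was near 0 for both, at -0.005 and -0.007.

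By the size rule 233 rows differed at 8 months, 131 higher and 102 lower in the female pool, and 171 had a symbol. Of all rows, 10.6% had 1 sign on the 4 arrays. From replicates 3 and 4 alone, with 1 sign asked of these 2 arrays only, 260 rows met the rule, and 121 rows were in both sets. Leaving out 1 array, with 1 sign then asked of 3 arrays, gave 378 rows without replicate 1, 376 without 2, 533 without 3 and 468 without 4. Erythroid markers had a median of 0.78 (percentile 100; 0.86 on replicates 3 and 4), with 2 genes higher by the size rule, Bpgm at 0.93 ± 0.23 and the anion exchanger Slc4a1 at 0.71 ± 0.08. Fatty acid oxidation genes had a median of -0.40 (percentile 0; -0.27 on replicates 3 and 4), with 2 genes lower by the size rule, Pdk4 at -0.75 ± 0.12 and Acaa2 at -0.61 ± 0.26. Interferon response genes had a median of 0.29 (percentile 100), with Usp18 at 0.54 ± 0.36 and Rsad2 at 0.53 ± 0.21, and none met the size rule. Immediate early genes had a median of 0.26 (percentile 99.8) with 3 genes higher by the size rule, among them Fos at 1.01 ± 0.69. Cell cycle genes had a median of -0.25 (percentile 0.06), with 20 of 21 negative and 2 lower by the size rule, Aurka and Ccne1, the latter at -0.71 ± 0.87. Ccne1 rests on replicate 1, which carries the trend, and on replicates 3 and 4 it was at -0.32, short of 1.5-fold, as was Acaa2 at -0.46. The median of the cell cycle genes was -0.20 there, that of the interferon response genes 0.28 and that of the immediate early genes 0.36.

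Among rows with a gene symbol, the sex ratio differed most between the ages, by the size rule, for Chil1 and for T cell genes. The difference of 8 minus 2 months was -3.41 for Dntt, -3.33 for Rag1, -3.33 for Cd8a, -3.32 for Tcrb-V8.2 and -3.23 for Lat, whose arrays of the 2 ages did not overlap. Among rows with no symbol it was -5.03 for probe 3559. In the other direction it was 4.27 for Chil1, 2.69 for Jchain, 2.37 for Lcn2, 2.31 for Ptgds, the prostaglandin D synthase, and 2.26 for E230024E03Rik. Ptgds was lower in the female pool at 2 months, at -0.72 ± 0.09, and higher at 8 months, at 1.59 ± 0.34. In all, 257 rows differed by at least 1.5-fold with no overlap, 123 with a higher ratio at 8 months and 134 with a lower one. Among the sex-linked genes Eif2s3y met this rule, with a difference of 1.31. Of all rows, 5.93% had no overlap.

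Antigen presentation and macrophage markers went from a median of -0.44 at 2 months to 0.22 at 8 months (0.20 on replicates 3 and 4), where 13 of 19 were positive. Extracellular matrix genes went from -0.22 to 0.082 (0.16 on replicates 3 and 4), with 4 genes higher by the size rule at 8 months, among them Timp1 and the thrombospondin gene Thbs1 at 1.05 ± 0.34. Clock genes went from a median of 0.12 to -0.32, or -0.15 on replicates 3 and 4. At 8 months Arntl, an activator of the clock, was higher in the female pool by 1.11 ± 0.22, and Per3 and Nr1d2, repressors in the clock, were lower at -1.004 ± 0.70 and -0.77 ± 0.71, while Clock, the partner of Arntl, was at -0.01 ± 0.97. On replicates 3 and 4 Arntl was at 0.99, Nr1d2 at -0.61 and Clock at 0.036. At 2 months Arntl was at -0.32 ± 0.14, Clock at -0.49 ± 0.11 and Per3 at 0.21 ± 0.05, the mean of probes that disagreed in sign, at -0.0623 and 0.486; those of Clock disagreed at 8 months, at -0.191 and 0.168. With the 8-month value from replicates 3 and 4 only, 470 rows met the age-difference rule in place of 257. Without replicate 1, 2, 3 or 4 at 8 months 490, 457, 391 or 407 rows met it. No overlap is easier to meet with fewer arrays, so these counts and the 470 cannot be set against 257.

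Across the 7812 rows the sex ratios of the 2 ages correlated with Pearson's r = 0.291 and Spearman's rho = 0.21, and with r = 0.272 and rho = 0.208 without the sex-linked lists. When the rows called over both ages were left out as well, r was 0.197. Genes are not independent replicates, so no p is given. By the size rule 23 rows were higher in the female pool at both ages, where independent lists would share 3.15, and 14 were lower at both, where they would share 1.80. The shared genes included Xist, Fxyd2, Cyp2b10, Gla, Nr4a1, Sftpc, Car5b and Rag1 on the female side and Kdm5d, Eif2s3y, Apcs, Stom, Nsmaf and Pdk4 on the male side, although Nsmaf at 8 months was at -0.12 on replicates 3 and 4. Opposite directions were found for 2 rows that were higher at 2 and lower at 8 months and for 6 rows that were lower at 2 and higher at 8 months, Ptgds and E230024E03Rik among the latter.

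**Figure D4:**
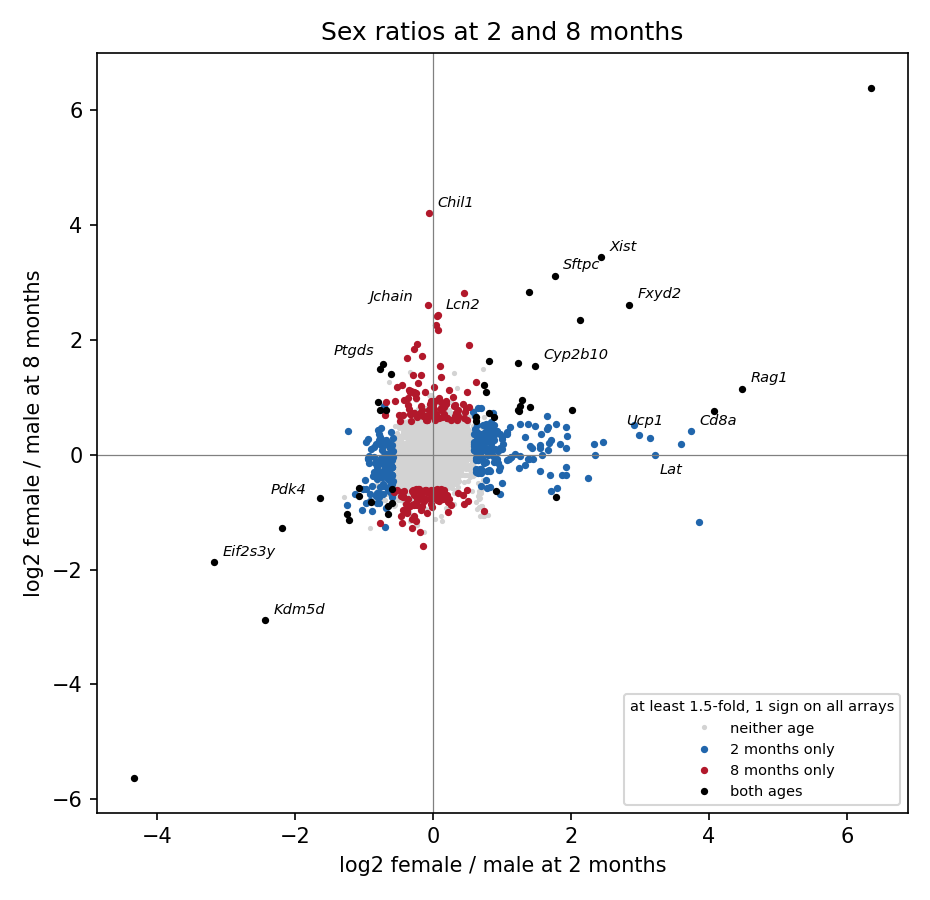
Log2 ratio of female over male at 8 months against that at 2 months, 1 point per row; colours mark rows of at least 1.5-fold with 1 sign on all arrays at 2 months, at 8 months or at both ages. The T cell genes Rag1 and Cd8a lie far to the right, Chil1 far up, and Xist, Kdm5d and Eif2s3y far from 0 at both ages.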

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

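The tests in this part were chosen after the results they measure were seen. Between the ages, 6 named genes and 3 gene lists went 1 way on all arrays of an age and the other way on all arrays of the other, and these differences were not tested across animals. The sex ratio of Ptgds differed by 2.31 (8 minus 2 months, log2), that of E230024E03Rik by 2.26, that of Arntl by 1.43, that of Thbs1 by 1.32, that of Slc4a1 by 1.04 and that of Per3 by -1.22. Of the 2 probes of Per3, 1 was negative at both ages, at -0.0623 and -0.809, and the other at 0.486 and -1.2. The median of the interferon response genes differed by 0.46, that of the adipocyte markers by -0.74 and that of the clock genes by -0.43. On replicates 3 and 4 the 8-month medians of these lists were 0.28, -0.14 and -0.15, against 0.29, -0.31 and -0.32 on all 4 arrays.

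The clock genes are the first pattern to weigh. At 8 months 3 measured genes of the Arntl phase exceeded 6 of the Per phase in the female pool by 1.04 on average, between 0.91 and 1.21 on the 4 arrays (exact permutation p = 0.0119 over 84 groupings of the genes, two-sided, the smallest p they can give, genes not being independent), and at 2 months the difference was -0.38. The trend along the feature number on replicates 1 and 2 does not account for it, since replicates 3 and 4 gave 0.95. A difference between the pools in the time of day at which hearts were taken predicts opposite shifts of the 2 phases, and the values do not decide it. Of the Per phase 4 of 6 genes were lower on all 4 arrays, but of the Arntl phase only Arntl was higher on all 4, with Nfil3 at 0.35 ± 0.77 and Clock at -0.01 ± 0.97 (log2, SD; 0.29 and 0.036 on replicates 3 and 4). The time of collection is not given in the sources used here. A sex difference of the heart clock that depends on age was not tested and stays open, as 1 pool per sex and age holds no spread between animals.

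In 311 groups of 4 arrays, 11 had 1 array far from the other 3, where chance gives about 15.6. For named genes at 8 months these were Cxcl5, with 0.58 on replicate 2, and Aurka, Ccne1 and Ppargc1a, with -2.0, -2.0 and 0.56 on replicate 1. At 2 months they were Ndufa1, with 0.061 on replicate 1, and Cnn1, with 0.64 on replicate 3. For medians of lists at 8 months they were 0.80 for X escape genes, -1.15 for glycolysis genes, -0.48 for calcium handling and ion channel genes and 0.38 for skeletal muscle markers. At 2 months it was 0.081 for xenobiotic metabolism genes.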

How the results depend on the processing

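Keeping values of 0, removing the trend along the feature number and taking 8 months from arrays 3 and 4 were chosen after the data were seen. No value changed its sign with a call. The 7 calls over both ages became 5 with each array centred on its median, 5 with robust eBayes, 3 after scaling the arrays to 1 spread (1 higher and 2 lower), 16 on rows with a value on all 8 arrays, 4 without the filter, 1 with the trend removed, and 1 with 8 months from arrays 3 and 4. It became 34 in limma on 8 arrays with a dye term and 114 with age as a random block; leaving out 1 array gave 4 to 105, the highest without replicate 4 at 8 months. The fits with 34 and 114 calls take technical arrays for replicates. The 105 calls rest largely on the variance prior that limma fitted, and for the other settings the cause was not tested. At 2 months the 326 rows became 579 after scaling, 767 at 1.3-fold, 87 at 2-fold and 1745 in array-level limma with a dye term, which held 294 of the 326; leaving out 1 array gave 318 to 371. At 8 months the 233 rows became 153 after scaling, 383 without the filter, 477 at 1.3-fold, 67 at 2-fold, 35 in array-level limma with a dye term and 15 without it; leaving out 1 array gave 228 to 533, the highest without replicate 3. The 257 rows of the age difference became 470 with arrays 3 and 4, 390 at 1.3-fold and 123 at 2-fold, and 279 to 490 when 1 array was left out, the highest without replicate 1 at 8 months. Since 1 sign and no overlap are easier to meet with fewer arrays, such counts cannot be set against the main ones. The correlation of the ages was 0.325 on rows with all 8 values, 0.239 with the female pool in Cy3, 0.335 with it in Cy5 and 0.238 to 0.309 when 1 array was left out. With 1 dye orientation alone, a dye effect shared by arrays of both ages does not cancel. The values for Cy3 and Cy5 therefore cannot be set against the main 0.291.

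For the age difference, array-level limma called 29 rows without and 19 with the replicate number as a block. The numbers mark the dye orientation and do not pair animals: arrays of the same number correlated in their deviations at -0.16, -0.10, 0.54 and 0.55, and 2 of the 4 correlated best with their own number. Of 9 list calls, 9 were also made with each probe on its own; adipocyte markers were called too at the probe level (camera adjusted p = 0.0138) and on all arrays (camera adjusted p = 0.011), and smooth muscle and pericyte markers with arrays 3 and 4 (camera adjusted p = 0.0154). For these 2 lists too the main values gave an adjusted p of 0.94 with an estimated correlation. Of 2625 values of named genes under 16 settings, 2540 were counted as unchanged, 20 lost and 42 gained a call, and 23 moved by more than their SD. A value over both ages counted as unchanged when its call stayed, whatever its size. If it was not called, it could also change its sign by less than its SD. Values at 1 age or between the ages counted as unchanged when they shifted by less than their SD. The 2540 therefore do not show that values over both ages kept their size. The table holds no signal over background, so its limit is unknown.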

Other observations

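The tests in this part were chosen after the results they measure were seen, on gene lists written after those results. Several lung and airway genes were higher in the 2-month female pool: Cyp2f2 was at 1.92 ± 0.21 (log2, SD, n = 4 arrays), Bpifb1 at 1.92 ± 0.19 and Scgb3a1 at 1.26 ± 0.09. Sftpd was at 1.07 ± 0.36 and Scgb1a1 at 0.66 ± 0.09, and 7 of 12 measured lung and airway genes met the size rule. Not all genes of the list followed. Sftpc was at 1.76 ± 0.31, but Napsa was at -0.26 ± 0.19, Slc34a2 at -0.23 ± 0.12 and Ager at -0.04 ± 0.20. Ctsh was at 0.15 ± 0.14 and Cyp2s1 at 0.14 ± 0.20. At 8 months the same list had a median of -0.034, with Cyp2f2 at -0.22, Bpifb1 at -0.35 and Scgb3a1 at -0.02. Chemokine and acute phase genes outside the rule for named genes, chosen after their values were seen, were at 1.40 ± 0.36 for Ccl7, 1.13 ± 0.60 for Ccl2, 1.44 ± 1.09 for Serpina3n, 1.39 ± 1.35 for Il1b and 1.39 ± 0.69 for Chil3 at 8 months, and at -0.61, -0.36, -0.34, -0.29 and -0.17 at 2 months. Of the 15 measured genes of the inflammation list outside that rule, 6 were positive at 2 months. Among them were Orm1 at 1.23 and Tnc at 0.74, against 0.77 and 1.21 at 8 months.

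The second pattern is the group of thymus and brown fat genes in the 2-month female pool. Of 13 measured genes of the thymus list outside the rule for named genes, 12 were positive, with a median of 1.65, and Thy1 was the exception at -0.24. Mature B and natural killer cells alone do not account for it. The 7 measured genes of the mature lymphocyte list had a median of 0.279 with an SD of 0.505 between genes. Each lay below the 1.65 of the thymus list by more than its SD over the arrays, the highest being Gzma at 0.91 ± 0.15. Mature T cells were not tested, because T cell genes such as Cd3e, Cd3g, Cd4 and Cd8a were counted on the thymus list. Of the naive T cell markers on the mature lymphocyte list Il7r alone was measured, at 0.29 ± 0.17. Thymus tissue taken with the hearts remains a candidate explanation. For brown fat the values do not decide: of the 5 measured genes of its list outside that rule 4 were positive, but their median of 0.417 was below the bound of 0.58 chosen for it. Of its named genes Ucp1 was at 2.99, Fasn at 1.88, Scd1 at 1.79, Cidec at 1.71 and Car3 at 1.33, but Elovl3 at -0.07. With these named genes the list had a median of 0.76, and 9 of its 11 measured genes were positive. Lists fixed earlier hold 8 of the 19 measured thymus genes and 9 of the 11 measured brown fat genes, and the ratios do not tell which of them heart muscle itself expresses. A biological difference of the sexes at 2 months stays open and untested, since each sex was 1 pool.

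The last pattern is the group of inflammation genes in the 8-month female pool. The median of the 19 measured genes was 0.89 on replicates 3 and 4, which lack the trend along the feature number. The list holds genes named for their size at 8 months, and without the named genes this median was 0.56. It stayed positive but fell below 0.58, so a contribution of the trend on replicates 1 and 2 stays open. Whether lung tissue in the pool contributed stays open, because the 12 measured genes of the lung and airway list went both ways around a median of -0.034 with an SD of 0.92 between genes (1.17 on replicates 3 and 4). Sftpc was at 3.12 ± 1.65 (log2, SD, n = 4 arrays), Napsa at 0.48 ± 0.69, Ager at 0.37 ± 0.43, Sftpd at 0.37 ± 0.48 and Slc34a2 at 0.35 ± 0.62, while Bpifb1 was at -0.35 ± 1.04, Cyp2f2 at -0.22 ± 0.58 and Scgb1a1 at -0.06 ± 0.87. On replicates 3 and 4 Sftpc was at 3.89, Sftpd at 0.31, Ager at 0.18, Napsa at 0.14, Scgb1a1 at 0.11 and Slc34a2 at 0.085. Cyp2f2 was at -0.63 and Bpifb1 at -0.65 there. All 15 genes of the list outside the rule for named genes were positive at 8 months, with a median of 0.78, against 6 of 15 at 2 months; on replicates 3 and 4 it was 0.56, below the bound of 0.58 chosen for it. Inflamed hearts among the females cannot be told apart from a difference of all females at this age, because the 6 hearts were pooled.

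For the age difference, chance cannot be excluded, because each age had 1 pair of pools. Splits of the 8 arrays cannot settle it, as the arrays are technical and differ by dye. Of the 35 splits, 3 gave as many rows: the real split with 257, that by the dye of the female pool with 530 and another with 1105. Each of the remaining splits gave 187 or fewer. The split by dye has no mean of both dye orientations and was counted on plain means. The split with 1105 rows followed the dye except for replicates 1 and 2 at 8 months, which were exchanged, and so points to a structure of the arrays. The probe-specific dye effect common to the arrays was measured after removal of the trend as the correlation of the Cy5 over Cy3 ratios with their mean at the other age, taken at 8 months from replicates 3 and 4. It was 0.413 to 0.512 on the 4 arrays at 2 months and 0.58 and 0.54 on replicates 3 and 4 at 8 months, but -0.05 and 0.19 on replicates 1 and 2 at 8 months. With the replicate number, which marks the dye, as a block, 19 rows differed between the ages.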
